A study of Mus musculus with 12 samples.

How the data were processed

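The values analysed here are the signal per gene and library in the table deposited by the authors, which has 24062 gene entries with 24060 names. Per the submitters' processing notes, reads were aligned to mm10 and Bowtie2 2.2.1 and limma 3.18.13 were used, and the step in which limma was used is not stated. The kit was the stranded TruSeq mRNA kit. The counting tool, the annotation and the strand setting are not given in the sources used here. The header holds a mean over all samples and Cook's distances, as DESeq2 writes them, so the division by size factors in the manner of DESeq2 is inferred from the header and is not stated by the authors. The mean column equals the mean of the 12 libraries (largest relative difference 1.81e-08). The 12 columns of Cook's distances were not used here. Of the names, 25 on 27 entries had been turned into dates by spreadsheet software and were kept as they stand and not named. In total 23655 entries matched a gene of GENCODE M21, the source of coordinates, transcript lengths and GC content. No mitochondrial gene was among the entries, so that list was not analysed here.

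Dividing each column by its own smallest step gave whole numbers for 100% of values (tolerance 0.01), taken as reads. These recovered reads served edgeR and DESeq2 as alternatives, and their calls are given beside those of limma. Totals of normalised counts per library were 10.229 to 10.573 M without stimulation, 10.211 to 10.757 M with C-178, 12.899 to 14.064 M with CMA and 11.867 to 12.584 M with C-178 plus CMA. The 10 most abundant genes held 10.44% to 13.09% of the reads. Rescaling by TMM moved the median log2 change of no comparison by more than 0.02, and shifts of single libraries were not computed. Between replicates of a group, variation was larger than counting noise in every case (chi-square per gene 2.46 to 113.05).

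Genes above 10 normalised counts in at least 3 of the 12 libraries were tested (11440 genes). Log2 of value + 1 was fitted with lmFit of limma 3.58.1 under R 4.3.3 over all 12 libraries, with eBayes and a mean-variance trend, and p values were adjusted by the method of Benjamini and Hochberg within each comparison, with calls at adjusted p under 0.05. The limma fit takes 1 spread per gene for all groups, so its SE and p values assume equal spread in the groups. edgeR 4.0.16 was used with quasi-likelihood tests and DESeq2 1.42.0 with its defaults. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used for reading the table and drawing. Of 32 gene lists written from general knowledge, 27 had at least 5 tested members and were tested with camera at a preset correlation of 0.01, with fry, and with camera at an estimated correlation. For CMA against no stimulation 8 lists were called at the preset and 0 at the estimated correlation (camera), for C-178 against no stimulation 9 and 1, for C-178 plus CMA against CMA 12 and 2, for C-178 plus CMA against C-178 9 and 0, for C-178 plus CMA against no stimulation 13 and 0, and for the interaction 8 and 0. The directional test of fry called 16, 1, 13, 14, 14 and 6 lists in the same order. The estimated correlation, taken from deviations within groups, was 0.47 for the interferon-stimulated and 0.145 for the NF-κB list, so the preset is low for them. For some lists it was under the preset, as for p53 targets (-0.00911).

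Genes named in the text were chosen by rule. For CMA and for C-178 against no stimulation, and for C-178 plus CMA against CMA and against C-178, these were the 10 largest rises and 10 largest falls among called genes whose groups did not overlap and whose mean reached 100 normalised counts over all libraries or in the higher group. For the interaction the 5 most positive and 5 most negative called genes were taken. Some genes that the rule names are not reported here. Fixed genes were added (Ifnb1, Ifna4, Ifit1, Ifit2, Isg15, Rsad2, Cxcl10, Ccl5, Tnf, Il6, Il1b, Nfkbia, Tnfaip3, Tmem173 and Hmox1), and up to 4 members of each list described, those with the smallest adjusted p. The marker genes named in the description of the data were chosen after their values were seen, as was the following of the C-178 genes into the comparison with CMA. A fold against a group without reads is a lower bound from a floor of 3 reads over the group. Such floors and the counting intervals cover counting error only.

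Library numbers were checked for pairing with residuals of tested genes. The C-178 and C-178 plus CMA libraries with the same number correlated at 0.45, 0.43 and 0.26, above the minimum of 0.1, so their numbers were taken to pair these groups. The residuals of a group sum to 0, so the 3 values are not independent. Both number 1 libraries were the deepest of their groups (28.476 and 36.438 M reads). The values therefore do not tell shared cultures from shared handling of the libraries. The CMA and C-178 plus CMA libraries correlated at -0.14, 0.18 and -0.16, and the C-178 and CMA libraries at -0.04, 0.06 and -0.08. The numbers were thus not taken to pair CMA with either, although 0.18 alone passes the minimum. No paired analysis was possible with the unstimulated group because 2 of its columns share a heading. Nothing in the labels says whether the 3 libraries of a group come from separate animals or cultures, so the p values measure only the spread between libraries, which may be technical.

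The pipeline was tested on simulated tables of 11440 genes with 200 changed genes. For CMA against no stimulation limma recovered 19.4%, 79.1% and 100% of genes changed 1.5-fold, 2-fold and 4-fold, with 6.38% false calls, and DESeq2 had 15.7% false calls. For C-178 plus CMA against CMA it recovered 23.9%, 67.2% and 100%, with 6.62% false calls (DESeq2 7.69%). For C-178 against no stimulation it recovered 16.4%, 82.1% and 95.5%, with 4.44% false calls (DESeq2 19.57%). When the members of the NRF2 list were shifted 1.5-fold, that list ranked first (adjusted p = 1.33e-35) and 0 other lists were called by camera. The simulation drew each gene independently, with the same dispersion in all groups. It therefore cannot show false list calls from correlated members, whose estimated correlation was 0.47 for the interferon-stimulated list. Nor do its rates of false calls cover groups of unequal spread.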

Results

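Messenger RNA was sequenced from primary bone marrow derived macrophages of C57Bl/6 mice in 4 groups of 3 libraries each. Cells were left unstimulated, or were given C-178 (a covalent inhibitor of STING, the adaptor that relays cytosolic DNA sensing), CMA (a small-molecule agonist of mouse STING), or C-178 together with CMA. The treated groups are labelled with a treatment time of 2 h. The labels number the libraries 1 to 3 in each treated group, and 2 of the 3 unstimulated columns share a heading, so the unstimulated libraries are called 1, a and b here. Reads recovered per library were 13.907, 17.449 and 16.168 M without stimulation, 28.476, 7.145 and 7.049 M with C-178, 7.826, 7.126 and 7.401 M with CMA, and 36.438, 8.813 and 7.766 M with C-178 plus CMA. All 3 CMA libraries were thus shallower than all 3 unstimulated libraries. Of 24062 gene entries, 16535 held at least a read in some library and 11440 passed the filter for testing. A floor of 3 reads over a group equals 0.6564 normalised counts for the unstimulated group and 1.8092 for CMA, 0.7244 for C-178 and 0.6864 for C-178 plus CMA. Levels are normalised counts with the SD of 3 libraries, and changes are log2 differences of value + 1 with their SE, which understate the fold change of genes with few reads.

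Transcripts of macrophages dominated the unstimulated libraries. All 25 macrophage markers checked were above 100 normalised counts there, with a median of 3920, and Lyz2, which encodes lysozyme, reached 211600. Neutrophil markers were lower (median 122, 7 of 13 above 100, Ngp highest at 366.8). So were lymphoid markers (median 4.46, Cd79b at 584.3, Cd4 at 434.2), dendritic cell markers (Batf3 at 64.3) and mast cell markers (Kit at 9.278). Of megakaryocyte markers, Pf4 stood at 343.8, Ppbp at 23.03 and Itga2b at 9.071. Fibroblast genes were present at a median of 88.8, with 7 of 15 above 100. Among them, Fn1 (fibronectin) stood at 689.3 and the collagen gene Col1a2 at 244.4 without stimulation, and at 1164 and 444.4 with CMA. Part of the label text on RNA extraction speaks of embryonic fibroblasts, so these genes were followed through each comparison. The first principal component held 66% of the variance and placed the CMA libraries at 62.3 to 76.5, the C-178 plus CMA libraries at 10.3 to 38.4, and the 6 libraries without CMA between -49.4 and -44.8. Replicates lay closest in the unstimulated group (median SD of log2 values 0.115) and furthest apart with C-178 plus CMA (0.34), against 0.179 with C-178 and 0.148 with CMA.

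CMA against no stimulation asks what the STING agonist alone switched on. Ifnb1, the interferon beta gene (chr4:88522025-88522774, minus strand, mm10), had no read in any unstimulated library and reached 1755 ± 407.9 normalised counts (SD, n = 3) with CMA, at least 2674-fold higher (log2 change 10.75 ± 0.36, adjusted p = 1.1e-10). Cxcl10, which encodes a T cell attracting chemokine (chr5:92346638-92348889, minus strand), rose 850.9-fold from 96.93 ± 28.99 to 82480 ± 10400 (log2 change 9.76 ± 0.21, adjusted p = 2.95e-12). Its neighbour Cxcl9 rose 1041-fold, from 24.04 ± 3.25 to 25020 ± 6935. Rsad2, which encodes the antiviral protein viperin (chr12:26442746-26456452, minus strand), went from 1630 ± 308.2 to 249900 ± 40450, a 153-fold rise. Tnfaip3, which encodes the NF-κB inhibitor A20 (chr10:19000910-19015657, minus strand), rose from 222.1 ± 14.52 to 4048 ± 814.1 (log2 change 4.16 ± 0.22).

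**Figure D1:**
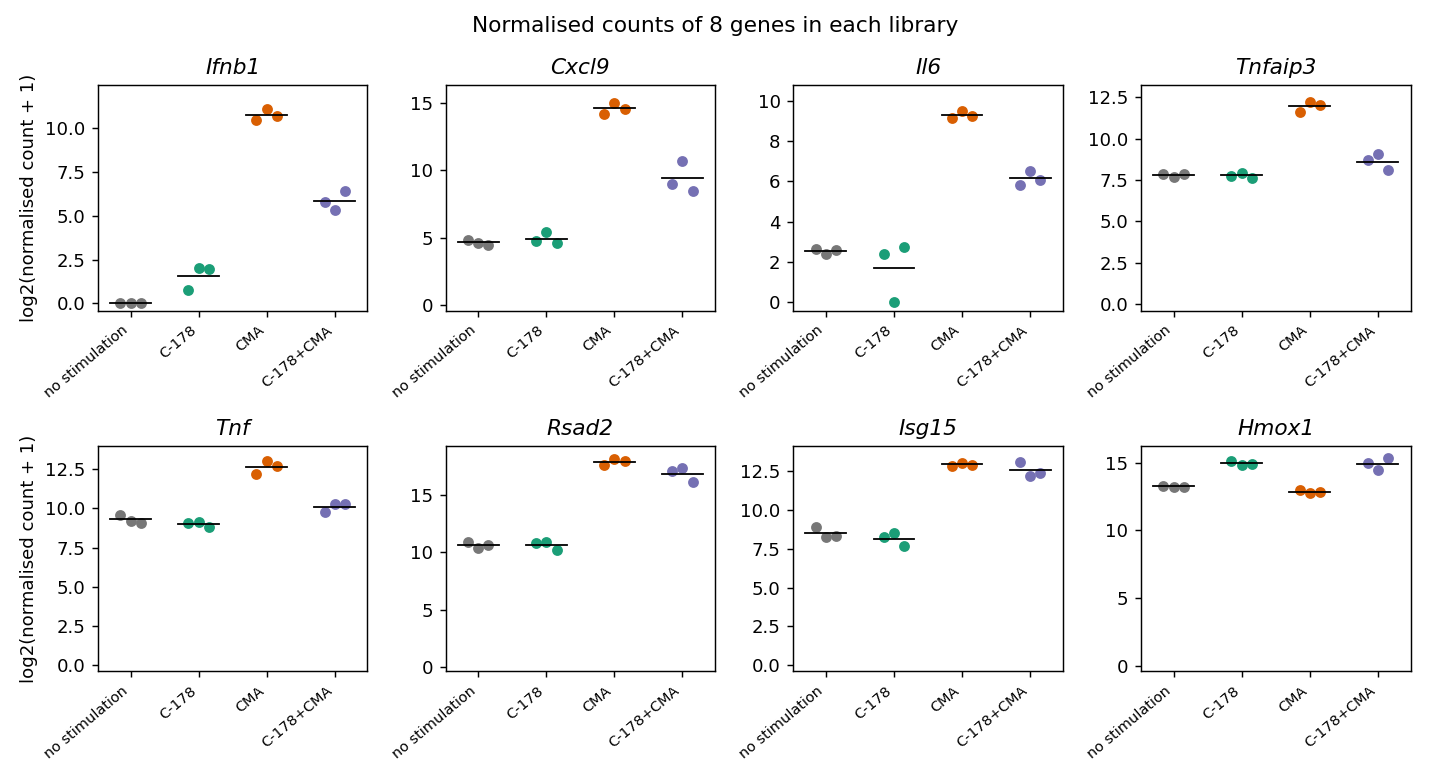
Normalised counts of interferon, NF-κB and oxidative stress genes in each of the 12 libraries, by group.

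Among the largest rises by CMA were the lymphocyte activation gene Cd69 (log2 change 9.31 ± 0.26), the serpin gene Serpina3f (8.32 ± 0.41) and Heatr9 (8.21 ± 0.42). Close behind were the guanylate binding protein gene Gbp5 (7.93 ± 0.30), the collagenase gene Mmp13 (7.83 ± 0.66) and Irg1, which encodes the enzyme that makes itaconate (7.82 ± 0.28). The interferon alpha gene Ifna4 was at least 67.7-fold higher and Ifna2 at least 45.4-fold higher, each with no read in the unstimulated group. Reads may be shared among the close copies of the interferon alpha genes, and among those of the serpin genes, since the counting rule is not given in the sources used here. Cxcl11 held 717 reads with CMA and 1 without, a ratio of 1980 (95% counting interval 354 to 78200). Further interferon-stimulated genes rose, among them Ifit1 (80.4-fold, 6.34 ± 0.27), Ifit2 (57.3-fold, 5.85 ± 0.28) and the ubiquitin-like modifier gene Isg15 (21.4-fold, 4.45 ± 0.25). The cytokine genes Il6 (130-fold, 6.75 ± 0.53), Tnf (10.2-fold, 3.33 ± 0.21) and Il1b (1.76-fold, 0.82 ± 0.16), the NF-κB inhibitor gene Nfkbia (5.69-fold, 2.51 ± 0.14) and the chemokine gene Ccl5 (16.4-fold, 4.06 ± 0.73) rose too. Tmem173, which encodes STING (chr18:35733679-35740554, minus strand), was not called at 624 ± 64.98 and 720 ± 38.04 (log2 change 0.21 ± 0.15, adjusted p = 0.293).

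The largest falls under CMA were those of the cell death gene Bmf (log2 change -5.92 ± 0.46, from 376.1 to 7.375), the myeloid receptor gene Cd300lb (-4.99 ± 0.25, from 3189 to 102.2) and the oxysterol receptor gene Gpr183 (-4.96 ± 0.43). The cannabinoid receptor gene Cnr2 (-4.51 ± 0.38) and the clock gene Nr1d1 (-4.44 ± 0.44) fell almost as far. Plekhg3 (-4.04 ± 0.22), the arrestin gene Arrdc3 (-3.84 ± 0.20), the stress-induced gene Sesn1 (-3.76 ± 0.16, from 4715 to 349.9), the transporter gene Slco4a1 (-3.75 ± 0.29) and the RNA decay gene Zfp36l2 (-3.75 ± 0.19) followed. In all, 2224 genes rose and 2047 fell, with 1259 and 863 of them at 2-fold or more. edgeR on recovered reads gave 2235 and 2047, and DESeq2 gave 2354 and 2031. With all reads thinned to the depth of the shallowest library 2150 genes rose and 1925 fell, 2088 and 1854 of them among those called at full depth. For 7073 genes (61.8%) the 2 groups did not overlap, where chance gives 10%. The fit was limma on log2 values of all 12 libraries. With 3 against 3 libraries no exact permutation p can fall under 0.1.

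Gene groups moved with CMA as follows, with camera at a preset correlation of 0.01. In the interferon-stimulated list, 59 of 60 tested members rose (59 adjusted over the list alone) with a median log2 change of 3.17 (adjusted p = 3.78e-42, and adjusted p = 0.0758 with an estimated correlation). Oasl1 (6.04), Ifi205 (7.44) and I830012O16Rik (5.40) were among them. Of 35 NF-κB target genes, 28 rose and 2 fell (28 and 2 over the list alone; median 1.44, adjusted p = 8.14e-13, and 0.0758 with an estimated correlation). Tnfsf15 (7.49), the receptor gene Cd40 (5.38 ± 0.30), Irf1 (3.82) and Peli1 (3.46) led this list. Among 19 chemokine genes, 12 rose and 1 fell (12 and 1 over the list alone; median 1.90), with Ccl4 at 5.85, Ccl2 at 4.56 and Ccl7 at 4.55 (adjusted p = 1.44e-06, and 0.0758 with an estimated correlation). Cytokine genes rose in 14 of 21 cases (14 up and 1 down over the list alone; median 1.88), with Tnfsf10 at 6.07 and Il27 at 5.70 (adjusted p = 6.31e-07, and 0.0758 with an estimated correlation). Feedback regulators of cytokine signalling, 7 of 10 up and 1 down (the same over the list alone; median 3.13), included Socs1 (7.18), Socs3 (5.76), Usp18 (4.24) and Pim1 (4.23), with adjusted p = 8.47e-05, and 0.24 with an estimated correlation. Antigen presentation genes rose in 12 of 21 cases (13 up and 1 down over the list alone; median 0.88, adjusted p = 8.47e-05, and 0.24 with an estimated correlation). They included the peptide transporter gene Tap1 (2.82 ± 0.18), Tapbp (1.53), the immunoproteasome gene Psmb10 (1.48) and H2-T23 (1.39).

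Genes of inflammasomes and cell death were 10 up and 3 down of 19 (the same over the list alone; median 0.55, adjusted p = 0.00786, and 0.248 with an estimated correlation). Casp4 (4.24), the necroptosis gene Mlkl (2.72), the DNA sensor gene Aim2 (2.39) and Casp1 (1.76) rose. Cholesterol synthesis genes were 3 up and 11 down of 23 (3 and 12 over the list alone; median -0.49, adjusted p = 0.0163, and 0.655 with an estimated correlation). Mvd (-1.11), Fdft1 (-0.87) and Msmo1 (-0.72) fell, and Insig1 (1.55), which encodes a brake on sterol synthesis, rose. The 13 tested fibroblast genes had a median of 0.67, and 3 rose and 1 fell, with Postn at 0.99 ± 0.28 and Thy1 at -2.31 (adjusted p = 0.26, not called). Their list mean was 7.027 and 6.852 in CMA libraries 2 and 3, but 6.306 in CMA library 1, below the unstimulated range of 6.314 to 6.46. Immediate early genes were split, with 13 up and 9 down of 30, a median of -0.24 and a mean of 0.35 (adjusted p = 0.677, not called). Genes of the STING pathway itself were 8 up and 5 down of 22, with the DNA sensor gene Mb21d1 (cGAS) at 3.07, the nuclease gene Trex1 at 2.04 and the receptor gene Ifnar1 at -0.91. Ribosomal protein genes had a median of 0.05, which turned to -0.27 with quantile normalisation, and none of the 42 was called.

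C-178 against no stimulation asks what the inhibitor did in resting cells. Hmox1, which encodes the heme-degrading enzyme heme oxygenase 1 (chr8:75093621-75100589, plus strand), rose 3.30-fold, from 9757 ± 240.6 to 32160 ± 2920 normalised counts (SD, n = 3; log2 change 1.72 ± 0.18, adjusted p = 0.00133). Slc40a1, which encodes the iron exporter ferroportin (chr1:45908068-45926523, minus strand), rose 2.52-fold, from 4739 to 11930 ± 180 (1.34 ± 0.17). Gclc, which encodes a subunit of the enzyme that starts glutathione synthesis (chr9:77754535-77794485, plus strand), rose 2.30-fold from 1088 ± 52.21 to 2503 ± 162.7 (1.20 ± 0.12). Srxn1, the sulfiredoxin gene (chr2:152105516-152111376, plus strand), rose 2.14-fold from 942.9 to 2020 ± 239.1 (1.09 ± 0.14), and the thioredoxin reductase gene Txnrd1 went from 2290 to 5446 (1.25 ± 0.14). The endothelin receptor gene Ednrb (3.80-fold, from 126.9 to 481.8, 1.90 ± 0.28) and Nanos1 (1.43 ± 0.22) rose, both at low levels. The glutathione reductase gene Gsr (0.91 ± 0.11), the glutathione synthesis gene Gclm (0.68 ± 0.11) and the unannotated transcripts A530064D06Rik (0.85) and B430306N03Rik (0.83) rose as well.

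**Figure D2:**
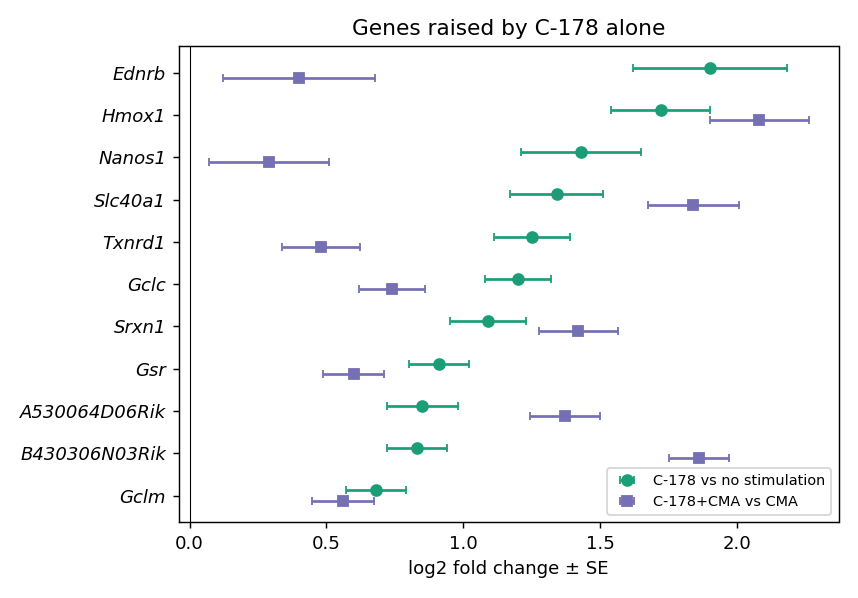
The genes called with C-178 against no stimulation, with their log2 change for C-178 alone and for C-178 plus CMA against CMA (error bars, SE).

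In total 11 genes rose with C-178, 7 of them at 2-fold or more, and limma called 0 falls. Without adjustment 238 genes were higher and 182 lower at 0.05, edgeR called 12 up and 1 down, and DESeq2 called 34 up and 4 down. The 2 groups did not overlap for 1779 genes (15.6%), where chance gives 10%. Across all genes the change tracked transcript length (Spearman rho 0.28) and GC content (-0.34). Trends shared by many genes can move that share away from 10% without an effect of the treatment. Ifnb1 (2.211 ± 1.295 with C-178, none without; log2 change 1.58 ± 0.36, adjusted p = 0.281), Socs3 (-0.94, adjusted p = 0.944) and Cd40 (-0.99, adjusted p = 0.857) were not called. Isg15 (-0.34), Tnf (-0.31), Il6 (-0.82), Rsad2 (-0.02) and Tmem173 (-0.27) each had adjusted p = 1. Calls for Ednrb, Gclm and Nanos1 were lost in 5, 11 and 6 of 26 alternatives, and those for Gsr (adjusted p = 0.0527) and Srxn1 (adjusted p = 0.0556) were lost without unstimulated library a. With array weights the counts became 823 and 1026.

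Targets of the antioxidant transcription factor NRF2 were the list that moved most with C-178, with a median of 0.46 and 6 of 30 genes up (18 over the list alone; camera adjusted p = 1.17e-36, and 0.000294 with an estimated correlation). By fry it was the only list called in this comparison (adjusted p = 0.000135). Cholesterol synthesis genes were shifted down without a single gene called among 23 (median -0.33; adjusted p = 6.27e-12, and 0.16 with an estimated correlation). Small shifts were also called for ribosomal protein genes (median -0.19, or -0.11 with the length and GC trend removed; adjusted p = 1.31e-05, and 0.511 with an estimated correlation) and antigen presentation genes (median -0.14, or -0.07 with that trend removed; adjusted p = 0.000678, and 0.384 with an estimated correlation). NF-κB targets (median -0.12; adjusted p = 0.00705, and 0.511 with an estimated correlation) and chemokine genes (median -0.22, or -0.09 on thinned reads; adjusted p = 0.00807, and 0.384 with an estimated correlation) shifted down without any gene called, also over the list alone. So did interferon-stimulated genes (median -0.09; adjusted p = 0.0145, and 0.739 with an estimated correlation). For the ribosomal list, library 2 of C-178 stood apart (list mean 10.317), with libraries 1 and 3 at 10.594 and 10.67 and the unstimulated ones at 10.616 to 10.775. Heat shock genes (median 0.07, 1 up over the list alone; adjusted p = 0.0332, and 0.549 with an estimated correlation) and fibroblast genes (median 0.34; adjusted p = 0.00329, and 0.511 with an estimated correlation) shifted up, with Col1a2 at 244.4 and 313.7.

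C-178 plus CMA against CMA asks how far the inhibitor held back the agonist response. Ifnb1 fell 29.6-fold, from 1755 ± 407.9 to 59.35 ± 22.5 normalised counts (SD, n = 3; log2 change -4.90 ± 0.36, adjusted p = 3.74e-06). Cxcl9 fell 29.8-fold, to 840.8 ± 721.1 (-5.19 ± 0.43, adjusted p = 7.77e-06). Tnfaip3 fell 10-fold, from 4048 ± 814.1 to 404.4 ± 132 (-3.35 ± 0.22, adjusted p = 1.03e-06). Tnf fell 5.77-fold, from 6533 ± 1726 to 1132 ± 225.1 (-2.51 ± 0.21), and Il6 fell 8.85-fold, from 631.3 ± 83.73 to 71.33 ± 18.35 (-3.15 ± 0.53). Cxcl10 fell only 2.68-fold, to 30810 ± 3817 (-1.42 ± 0.21), and Isg15 was not called at 7907 ± 489.4 and 6334 ± 2098 (-0.37 ± 0.25, adjusted p = 0.291).

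Other large falls were those of the protease gene Fap (log2 change -4.46 ± 0.68, from 349.4 ± 156.9 to 20.82 ± 20.23), the cytoskeletal GTPase gene Rnd3 (-4.07 ± 0.24), Socs3 (-4.01 ± 0.30) and the integrin gene Itga1 (-3.67). Mmp13 (-3.61 ± 0.66), the translation stress gene Ppp1r15a (-3.57 ± 0.13, from 5257 to 443.6), Tnn (-3.46) and Serpina3h (-3.46) followed. Ifna4 had 2 reads with both compounds and 71 with CMA, 93.6-fold fewer after scaling (95% counting interval 25 to 788). Nfkbia (-1.86 ± 0.14), Il1b (-1.57 ± 0.16) and Ifit2 (-1.37 ± 0.28) fell. Rsad2 (1.97-fold, -1.06 ± 0.28, adjusted p = 0.0173) and Ifit1 (-1.12 ± 0.27, adjusted p = 0.0105) fell in the full fit. With only the 2 groups they were not called (adjusted p = 0.108 and 0.0539), and over all alternatives the adjusted p of Rsad2 and Ifit1 ran from 0.0029 to 0.108 and 0.000832 to 0.0539. The largest rises were those of genes that CMA had lowered or C-178 had raised: Bmf (3.64 ± 0.46), Cnr2 (3.14 ± 0.38), Cd300lb (2.89 ± 0.25), Arrdc3 (2.57 ± 0.20) and Hmox1 (4.34-fold, 2.08 ± 0.18). Next were Nr1d1 (1.95 ± 0.44, not called with only the 2 groups, adjusted p = 0.0725), the lysosomal regulator gene Tfeb (1.95 ± 0.28), Plekhg3 (1.85), Slc40a1 (1.84) and Cebpa (1.77 ± 0.36). Ccl5 was not called (-0.51 ± 0.73, adjusted p = 0.627): its libraries with both compounds read 2182.6, 2728.7 and 34420.4, so its mean was higher than with CMA while its log2 change was negative. Tmem173 was not called either (-0.31 ± 0.15, adjusted p = 0.131).

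In this comparison 1217 genes rose and 1543 fell, 256 and 644 of them at 2-fold or more, and 4057 genes (35.5%) had groups that did not overlap, where chance gives 10%. edgeR called 1350 and 1405, and DESeq2 1422 and 1646. The counts were 597 and 747 without CMA library 2. With only the 2 groups they were 261 and 593, where the log2 changes are the same and only the estimate of the spread differs. The full fit shares 1 spread per gene over all groups, although their median SD ran from 0.115 (no stimulation) to 0.34 (C-178 plus CMA). Its SE and p values may thus be too small for comparisons with C-178 plus CMA and too large for the others. The balance turned with the scaling, at 1405 up and 1303 down with quantile normalisation and 1286 and 1103 with the length and GC trend removed. Of the 11 genes called with C-178 alone, 9 also rose here (1.2 by chance), and Ednrb (0.40, adjusted p = 0.294) and Nanos1 (0.29, adjusted p = 0.334) did not.

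NF-κB targets fell most evenly, 30 of 35 down (31 over the list alone; median -1.07, adjusted p = 3.2e-18, and 0.034 with an estimated correlation). Tnfsf15 (-3.34), the adhesion gene Icam1 (-1.85) and the apoptosis inhibitor gene Birc3 (-1.75) fell with them. NRF2 targets rose in 17 of 30 cases (20 up and 1 down over the list alone; median 0.58, adjusted p = 1.56e-09, and 0.034 with an estimated correlation), among them Srxn1 (1.42), Gclc (0.74), Gsr (0.60), Gclm (0.56) and Txnrd1 (0.48). Interferon-stimulated genes were 34 down and 2 up of 60 (37 and 2 over the list alone; median -0.72, adjusted p = 8.22e-10, and 0.435 with an estimated correlation). The median was -0.45 with quantile normalisation. The RNA sensor gene Ifih1 (-1.87), Ifi205 (-1.49) and Gbp2 (-1.35) were among those that fell. Chemokine genes fell in 11 of 19 cases (12 down and 1 up over the list alone; median -0.82), including Cxcl11 (-3.41 ± 0.41), Ccl3 (-2.20) and Ccl4 (-1.71); adjusted p = 1.78e-05, and 0.118 with an estimated correlation. Cytokine genes were 9 down and 1 up of 21 (the same over the list alone; median -0.71), with Il1a at -3.08 (adjusted p = 5.65e-05, and 0.168 with an estimated correlation). Immediate early genes were 17 down and 3 up of 30 (the same over the list alone; median -0.65, adjusted p = 7.62e-05, and 0.378 with an estimated correlation). Maff (-3.36), Egr1 (-2.12), Jun (-1.94) and Zfp36 (-1.45) fell.

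A smaller shift was called for feedback regulators of cytokine signalling (4 of 10 down, 4 over the list alone; median -0.49, or -0.31 with quantile normalisation, adjusted p = 0.00725, and 0.415 with an estimated correlation). Cholesterol synthesis genes such as Insig1 (-1.52) and Cyp51 (-1.07) were lower too (8 of 23 down, 10 over the list alone; median -0.29, adjusted p = 0.00832, and 0.522 with an estimated correlation). Autophagy and lysosome genes such as Sqstm1 (1.06) and Gabarapl1 (0.60) were shifted up (5 of 23 up, 5 over the list alone; median 0.19, adjusted p = 0.0133, and 0.202 with an estimated correlation). Ribosomal protein genes had a median of 0.28, with Rpl9 at 0.60 and Rpl18 at 0.92 among 42 (2 up, 0 over the list alone by limma; adjusted p = 0.0133, and 0.572 with an estimated correlation). Library 1 of C-178 plus CMA stood apart for this list (mean 11.373), with libraries 2 and 3 at 10.725 and 10.941 and CMA at 10.683 to 10.886 (exact permutation p = 0.2). Of 27 alternatives, the call for Rpl18 was lost in 17 and that for Rpl9 in 4. Fibroblast genes fell in 4 of 13 cases (4 over the list alone; median -0.49), among them Postn (-1.05), Dcn (-0.83) and Col5a1 (-0.89), with adjusted p = 0.0407, and 0.572 with an estimated correlation. Their list means overlapped between the groups (exact permutation p = 0.3). Libraries 1 and 2 of C-178 plus CMA (6.361 and 6.609) were within the CMA range of 6.306 to 7.027, and library 3 (5.794) was below it. The calls for Postn, Dcn and Col5a1 were lost in 3, 7 and 8 of 27 alternatives. Cell cycle genes were 5 down and 1 up of 30 (the same over the list alone; median -0.31), with Mki67 at -1.58 (adjusted p = 0.0415, and 0.572 with an estimated correlation). That shift lay in library 3 of C-178 plus CMA (list mean 6.183), as libraries 1 and 2 (7.437 and 7.419) were within the range of the CMA libraries (7.377 to 7.577; exact permutation p = 0.3). The calls for Mki67 and Gabarapl1 were each lost in 3 of 27 alternatives. Across all genes the change tracked transcript length (Spearman rho -0.30) and GC content (0.40), which bears on lists of short transcripts such as Rpl9 and Rpl18.

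C-178 plus CMA against C-178 asks what the agonist still did in the presence of the inhibitor. Cxcl10 rose 421-fold, from 73.27 ± 14.25 to 30810 ± 3817 normalised counts (SD, n = 3; log2 change 8.71 ± 0.21), and Rsad2 rose 78.3-fold, from 1618 ± 376.8 to 126700 ± 50030 (6.23 ± 0.28). Isg15 rose from 294.1 ± 87.03 to 6334 ± 2098 (4.42 ± 0.25), close to its change without the inhibitor. Ifnb1 rose 26.8-fold, from 2.211 ± 1.295 to 59.35 ± 22.5 (4.27 ± 0.36, adjusted p = 1.22e-06). Tnf (1.13 ± 0.21), Tnfaip3 (0.83 ± 0.22, adjusted p = 0.0123) and Nfkbia (0.61 ± 0.14, adjusted p = 0.00648) rose far less than without C-178. With only the 2 groups the calls for Tnfaip3 and Nfkbia were lost, with an adjusted p of up to 0.0739 and 0.0721 over all alternatives. Ifna4 was under the floor of 3 reads in both groups, so no fold is given, and Ifna2 held 5 reads with both compounds and none with C-178.

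The largest rises here were, after Cxcl10, those of Cd69 (log2 change 7.75 ± 0.26), Socs1 (7.72 ± 0.44), Serpina3f (7.55), the nucleotide kinase gene Cmpk2 (6.36 ± 0.31), Serpina3g (6.20), Gbp5 (6.18), Ccl12 (6.14) and Gbp11 (5.96). Ifit1 (5.27), Ifit2 (4.41), Il6 (4.42 ± 0.53) and Ccl5 (3.67 ± 0.73) rose. Kcnj2, a potassium channel gene, fell most (-3.81 ± 0.22, from 499.3 to 35.48), followed by Gpr183 (-3.37), Nuak1 (-2.93) and the growth factor gene Pdgfb (-2.87). Further falls were those of St8sia4 (-2.68), Kctd12b (-2.59), Utp14b (-2.52), Zfp36l1 (-2.51) and Nr1d1 (-2.50). Il1b fell (-0.48 ± 0.16, adjusted p = 0.0381), a call that was lost with a replicate block (adjusted p = 0.118) and whose adjusted p ran from 0.003 to 0.247 over all alternatives. Hmox1 (-0.03) and Tmem173 (0.17, adjusted p = 0.421) were not called. In all 1548 genes rose and 1440 fell (1563 and 1460 with a replicate block), 660 and 445 of them at 2-fold or more. edgeR gave 1737 and 1402 and DESeq2 gave 1836 and 1542. The groups did not overlap for 3887 genes (34%), where chance gives 10%.

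All 60 interferon-stimulated genes tested rose with the agonist under C-178 (60 over the list alone; median 2.53, adjusted p = 7.38e-53, and 0.0843 with an estimated correlation). Antigen presentation genes rose in 18 of 21 cases (18 over the list alone; median 1.23), with Tap1 at 2.57, Psmb10 at 1.99, Psmb9 at 1.93 and H2-T23 at 1.64 (adjusted p = 3.49e-12, and 0.0843 with an estimated correlation). Chemokine genes were 10 up and 2 down of 19 (the same over the list alone; median 2.37, adjusted p = 1.17e-05, and 0.102 with an estimated correlation). Cytokine genes were 10 up and 1 down of 21 (10 and 2 over the list alone; median 0.74, adjusted p = 0.000142, and 0.205 with an estimated correlation). NF-κB targets were 14 up and 3 down of 35 (18 and 4 over the list alone; median 0.55), with adjusted p = 0.000703, and 0.379 with an estimated correlation. Feedback regulators such as Socs1 rose in 7 of 10 cases (7 over the list alone; median 1.61, adjusted p = 2e-04, and 0.288 with an estimated correlation). Genes of inflammasomes and cell death were 9 up and 2 down of 19 (the same over the list alone; median 0.29, adjusted p = 0.00605, and 0.288 with an estimated correlation). Ribosomal protein genes, led by Rps29 (1.23) and Rpl9 (0.91), rose in 13 of 42 cases (13 over the list alone; median 0.53, adjusted p = 2.49e-05, and 0.556 with an estimated correlation). Cholesterol synthesis genes fell in 8 of 23 cases (8 down and 1 up over the list alone; median -0.32, or -0.56 with the length and GC trend removed, adjusted p = 0.00222, and 0.497 with an estimated correlation). The change across all genes tracked transcript length here too (Spearman rho -0.28), and the median of the ribosomal protein genes was 0.30 with the length and GC trend removed and 0.32 with quantile normalisation. Library 1 of C-178 plus CMA (list mean 11.373, others 10.725 and 10.941) and library 2 of C-178 (10.317, others 10.594 and 10.67) stood apart for that list. The fibroblast genes were not called (median -0.45, adjusted p = 0.136).

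The 2 agonist comparisons share no library. Across all tested genes their log2 changes correlated at r = 0.75 (Spearman rho 0.50), with a slope of 0.54, and 63.5% of genes had the same sign. Of the genes that rose with CMA, 958 also rose in the presence of C-178 (300.9 expected), among them Cxcl10, Rsad2 and Ifnb1, and 891 fell in both (257.7 expected). Among 1259 genes raised at least 2-fold by CMA, such as Ifnb1 and Tnfaip3, 803 (63.8%) were lower with C-178 plus CMA than with CMA, 8 were higher and 448 were neither. The genes were selected on the CMA and unstimulated libraries, which biases that share upward and the median change by CMA alone away from 0, for the raised and the lowered genes alike. Of the same 1259 genes, 733 (58.2%) still rose in the comparison with C-178, where the median log2 change was 0.91 against 1.86. Of 863 genes lowered at least 2-fold by CMA, such as Bmf and Cd300lb, 443 (51.3%) were higher with both compounds than with CMA, and 497 (57.6%) still fell under C-178 (median -0.77 against -1.46).

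C-178 plus CMA against no stimulation compares the jointly treated cells with resting cells. Both the agonist response and the response to C-178 were present: Cxcl10 stood at 30810 ± 3817 against 96.93 ± 28.99, Rsad2 at 126700 ± 50030 against 1630 ± 308.2, and Hmox1 at 32280 ± 9350 against 9757 ± 240.6 (SD, n = 3). In all 1265 genes rose and 1199 fell, 630 and 463 of them at 2-fold or more (edgeR 1506 and 1262, DESeq2 1626 and 1363). Interferon-stimulated genes rose in 59 of 60 cases (60 over the list alone; median 2.44, adjusted p = 1.83e-56, and 0.0834 with an estimated correlation). Antigen presentation genes rose in 14 of 21 (17 over the list alone; median 0.94, adjusted p = 1.93e-10, and 0.0834 with an estimated correlation). NRF2 targets such as Hmox1 rose in 13 of 30 cases, with 3 down (15 and 3 over the list alone; median 0.44, or 0.26 with the length and GC trend removed, adjusted p = 0.000341, and 0.129 with an estimated correlation). Cholesterol synthesis genes fell in 15 of 23 cases (16 over the list alone; median -0.73), and Hmgcs1 went from 1321 to 550.6 (adjusted p = 9.25e-08, and 0.168 with an estimated correlation). Fibroblast genes were not called (median -0.06, or 0.04 on thinned reads, adjusted p = 0.638).

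The interaction of C-178 and CMA asks whether the agonist response differed with and without the inhibitor. Ifnb1 (log2 difference of responses -6.49 ± 0.51, adjusted p = 2.64e-05), Cxcl9 (-5.46 ± 0.61), Fap (-4.97 ± 0.96), Tnn (-4.44 ± 0.68) and Rnd3 (-4.05 ± 0.34) lost most of their response. Tnfaip3 (-3.33 ± 0.31, adjusted p = 6.49e-05), Ppp1r15a (-3.85 ± 0.19), Tnf (-2.21 ± 0.29) and Nfkbia (-1.90 ± 0.20) had smaller rises with the inhibitor, while Il1b (-1.30 ± 0.22) rose with CMA alone (0.82 ± 0.16) and was lower with CMA under C-178 (-0.48 ± 0.16), a call lost in 16 of 29 alternatives, among them the replicate block (adjusted p = 0.118). Bmf (3.73 ± 0.64), Cnr2 (3.12 ± 0.54), Cd300lb (2.65 ± 0.35), Arrdc3 (2.47 ± 0.29) and Tfeb (2.15 ± 0.39) had smaller falls. Isg15 (-0.03, adjusted p = 0.964), Rsad2 (-1.03, adjusted p = 0.101), Ifit1 (-1.08, adjusted p = 0.0813), Il6 (-2.33 ± 0.75, adjusted p = 0.0614), Ccl5 (-0.40, adjusted p = 0.814) and Hmox1 (0.36, adjusted p = 0.34) were not called. Cxcl10 (-1.05 ± 0.30, adjusted p = 0.0411) and Ifit2 (-1.44 ± 0.40, adjusted p = 0.0387) were called, and were lost in 12 and 13 of 25 alternatives. Ifna4 (-5.07) was called and was lost in edgeR (adjusted p = 1). In all 452 genes had a positive and 685 a negative interaction, 239 and 463 of them at 2-fold or more (edgeR 541 and 642, DESeq2 778 and 986). The interaction tracked transcript length (Spearman rho -0.34) and GC content (0.45) across all genes. With that trend removed 323 and 446 genes were called, and only 220 and 380 of the main calls were kept.

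**Figure D3:**
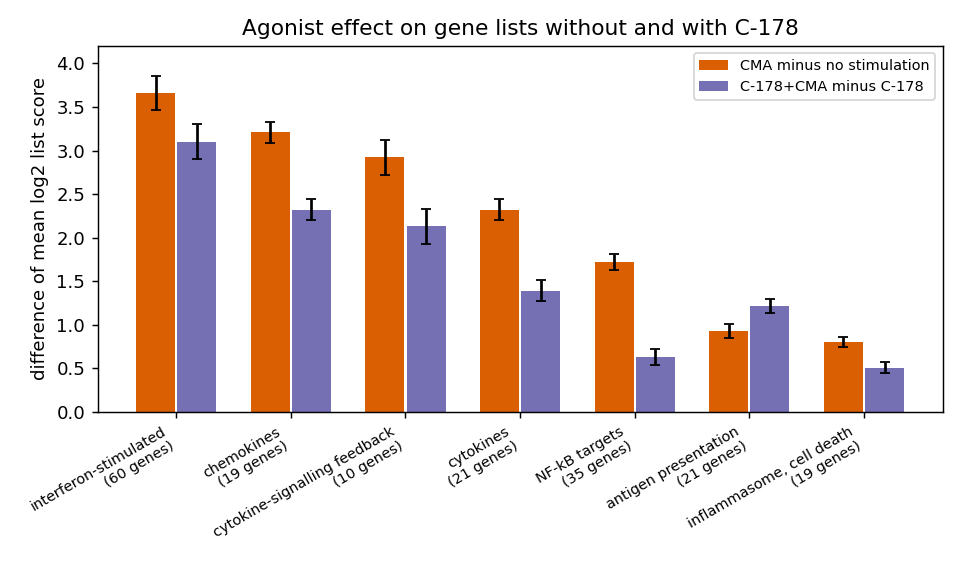
Mean log2 change by CMA without and with C-178 for the members of each gene list (error bars, SE).

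By list, the share of the agonist response kept under C-178 is given as a ratio of mean log2 changes, not of folds. NF-κB targets kept 36.5 ± 5.6% (SE) of their mean response (0.63 ± 0.09 with C-178 and 1.72 ± 0.09 without). Interferon-stimulated genes kept 84.5 ± 7.0% (3.10 ± 0.20 and 3.66 ± 0.20). Chemokine genes kept 72.2 ± 4.6%, cytokine genes 59.8 ± 5.9%, feedback regulators 72.9 ± 8.6%, inflammasome and cell death genes 63.5 ± 9.4% and antigen presentation genes 131.4 ± 14.1%. For antigen presentation genes the list means overlapped, at 10.68 to 10.77 with CMA and 10.65 to 11.01 with both compounds (exact permutation p = 0.6). Their mean was 9.6 with C-178 alone and 9.79 without stimulation, so the high share rests in part on a lower start. The list mean of NF-κB targets was 9.94 to 10.31 in the CMA libraries and 8.86 to 9.03 with both compounds, and that of interferon-stimulated genes was 13.221 to 13.513 and 12.312 to 12.998. Neither set of library means overlapped, which has an exact permutation p of 0.1, the smallest that 20 assignments allow. In the interaction, NF-κB targets had a median of -0.92 (16 of 35 negative, 22 over the list alone; adjusted p = 2.35e-13, and 0.163 with an estimated correlation), with Tnfsf15 at -2.95, Icam1 at -1.58 and Birc3 at -1.61. Interferon-stimulated genes had a median of -0.63, or -0.35 with quantile normalisation (8 of 60 negative and 1 positive, 21 and 2 over the list alone; adjusted p = 1.93e-05, and 0.573 with an estimated correlation). Cytokine genes such as Il1a (-3.58) had a median of -0.59 (7 of 21 negative and 1 positive, 10 and 1 over the list alone; adjusted p = 0.00248, and 0.509 with an estimated correlation). The median of chemokine genes was -0.53 (6 of 19 negative, 6 over the list alone; adjusted p = 0.00302, and 0.509 with an estimated correlation), and that of immediate early genes was -0.53 (10 of 30 negative and 2 positive, 13 and 2 over the list alone; adjusted p = 0.00442, and 0.573 with an estimated correlation). Fibroblast genes had a median of -0.85 (1 of 13 negative, 5 over the list alone, camera adjusted p = 0.00714, and 0.573 with an estimated correlation). For that list, library 3 of C-178 plus CMA (mean 5.794, others 6.361 and 6.609) and library 1 of CMA (6.306, others 7.027 and 6.852) stood apart. Antigen presentation genes such as H2-Aa (1.37, lost in 4 of 25 alternatives) had 0.30, or 0.52 with quantile normalisation and 0.14 with the length and GC trend removed (3 of 21 positive, 7 up and 1 down over the list alone; adjusted p = 0.0242, and 0.573 with an estimated correlation). Ribosomal protein genes had 0.46 (1 of 42 positive, 0 over the list alone by limma; adjusted p = 0.000506, and 0.573 with an estimated correlation), with library 1 of C-178 plus CMA at 11.373 and library 2 of C-178 at 10.317 apart from the others of their groups.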

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

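The groups, comparisons, gene lists and most alternatives were chosen before the data were examined, whereas the tests of transcript length and GC content in this part, and that of sequencing depth for the interferon-stimulated and NF-κB lists, were chosen only after the result was seen. What marked all of the results here was the interaction term, by which the response to CMA differed with and without C-178. It was called for 452 genes with a positive and 685 with a negative difference. With the length and GC trend removed 323 and 446 genes were called, and only 220 and 380 of the main calls were kept. Log2 differences of the responses in the main fit follow. Among genes raised by CMA, the response was smaller with C-178 for Ifnb1 (-6.49), Cxcl9 (-5.46), Ifna4 (-5.07), Fap (-4.97), Tnn (-4.44), Rnd3 (-4.05), Tnfaip3 (-3.33), Tnf (-2.21), Nfkbia (-1.90), Ifit2 (-1.44) and Cxcl10 (-1.05). The calls for Ifit2 and Cxcl10 were lost in 13 and 12 of 25 alternatives, and that for Ifna4 in edgeR (adjusted p = 1). For Il1b (-1.30) a rise with CMA alone (0.82) stood against a change of -0.48 under C-178, whose call was lost with a replicate block (adjusted p = 0.118) and in 16 of 29 alternatives. Among genes lowered by CMA, the fall was smaller for Bmf (3.73), Cnr2 (3.12), Cd300lb (2.65), Arrdc3 (2.47) and Tfeb (2.15). By list, the median difference was -0.92 for NF-κB targets, -0.85 for fibroblast genes, -0.63 for interferon-stimulated genes, -0.59 for cytokine genes, -0.53 for chemokine genes, -0.53 for immediate early genes, 0.30 for antigen presentation genes and 0.46 for ribosomal protein genes. With an estimated correlation camera called none of these 8 lists (the smallest adjusted p was 0.163), and the median of the interferon-stimulated genes was -0.35 with quantile normalisation. Of these lists fry called NF-κB targets (adjusted p = 0.000647) and chemokine and cytokine genes (0.00649 each). It did not call the others, such as interferon-stimulated (0.159), ribosomal protein (0.159) and fibroblast genes (0.109).

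Regroupings of the 12 libraries were used to ask how often the interaction calls arise by another assignment of libraries. The real grouping called 1137 genes. Of 100 regroupings, including the real one, 3 called as many, and the highest other called 1622. Of the 99 drawn, 6 called any gene and the median was 0. Shuffling mostly puts libraries with and without CMA into the same group, so the CMA effect enters the spread within groups. Low counts are then built in. The same holds for the splits of 2 groups below, where every other split mixes the groups and a large real difference enters the spread. The low counts therefore do not measure how often such calls arise by chance. The 2 drawn ones with as many calls (1622 and 1550) each placed 5 of the 6 CMA-treated libraries on the same side of the contrast, but 7 others with 5 or 1 on that side called at most 1 gene, so what raised the 2 counts was not determined. Neither the regroupings nor the fit of the interaction used the pairing of the C-178 and C-178 plus CMA libraries by number. For the comparisons of 2 groups there are only 10 splits, so the share with as many calls can never be under 0.1: the real split alone called as many, 1 of 10 each time, with 4271 genes against a highest other of 0 for CMA against no stimulation, 11 against 2 for C-178 against no stimulation, 2760 against 0 for C-178 plus CMA against CMA, 2988 against 0 for C-178 plus CMA against C-178, and 2464 against 0 for C-178 plus CMA against no stimulation.

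On the log2 scale, interferon-stimulated genes kept 48.0 ± 9.0 percentage points (SE) more of their agonist response under C-178 than NF-κB targets did. The share is a ratio of log2 changes with unlike denominators (3.66 and 1.72), and the interaction itself was -0.57 ± 0.28 and -1.09 ± 0.13. The SE takes the lists as independent, although both come from the same 12 libraries. The interferon-stimulated minus the NF-κB list mean was 0.56 log2 higher with C-178 plus CMA than with CMA. Its exact permutation p was 0.1, the smallest that 20 assignments allow. Transcript length and GC content did not account for the 48.0 points, as the difference was 54.3 points with that trend removed. Neither did depth, as the difference was 49.1 points with reads thinned to the shallowest library. The size of the agonist effect was tested on the difference in interaction in log2, not on the percentage points. The larger effect and the level of the interferon-stimulated genes did not account for that difference. It was 0.72 between 59 interferon-stimulated and 28 NF-κB genes, where 2137 background genes of neither list predicted -0.37. The SE of the gap between the observed and the predicted difference was 0.14. That SE takes genes as independent, although the estimated correlation within the interferon-stimulated list was 0.47. The groups of the design leave a biological difference between the 2 sets of genes as a possible reading, for example that less STING activity is needed for the interferon-stimulated genes (Isg15, Rsad2) than for the NF-κB targets (Tnfaip3, Nfkbia), and no test here separates that from an action of C-178 outside STING. The value of 54.3 points excludes only what it was computed for.

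The 3 libraries with C-178 plus CMA lay further apart than those of any other group, with a median SD of 0.34 log2 against 0.115 to 0.179. The spread was 0.311 with the length and GC trend removed, 0.351 with reads thinned to the same total, and 0.292 with the deviation of the C-178 library of the same number regressed out, so none of these brought it to the level of the other groups. Ccl5 (2182.6, 2728.7 and 34420.4) and Cxcl9 (840.8 ± 721.1) were among the genes that varied, and genes were not ranked by their spread. Deviations of library 2 from the group mean followed the CMA effect across genes (r = 0.39) and transcript length (rho 0.42). Those of library 3 went the other way (-0.3 and -0.35), and those of library 1 followed neither (-0.03 and -0.01). Deviations within a group are not independent. Library 3 also had the fewest genes with a read of all libraries (12962, against 13320 in the shallower C-178 library 3). The cause was not tested, so what made these libraries differ stays open.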

How the results depend on the processing

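The thinning of reads, the removal of the length and GC trend, the fit without the 2 deepest libraries, the combinations of these with a replicate block, and the gene list tests after TMM rescaling were chosen only after the result was seen. Among the named genes none that was called reversed, and no called gene list reversed under the alternatives tried for lists, which left out no library, while 1 gene called for CMA against no stimulation was called in the opposite direction with quantile normalisation. Counts within a factor of 1.5, shares within the SD between libraries and correlations within their SE over left-out libraries were rated the same. So rated were, for example, 2047 falls for CMA against no stimulation in the main fit and 2667 with quantile normalisation. Of the counts, shares and correlations recomputed, 287 stayed the same by this rule and 67 moved under the alternatives chosen before the data were examined. Under the later ones 64 stayed the same and 3 moved. Of 364 values of named genes in a comparison 293 were called, 253 of these in every alternative, and 40 were lost in at least 1 (5 only when a library was left out). For CMA against no stimulation, array weights gave 3672 genes higher and 3708 lower, and the 2 groups alone 3075 lower. For C-178 against no stimulation, the counts were 17 and 1 with quantile normalisation, 823 and 1026 with array weights, 27 and 4 with the 2 groups alone, 12 and 1 in edgeR, 34 and 4 in DESeq2, and 8 lower without the 2 deepest libraries. For C-178 plus CMA against CMA, the 2 groups alone gave 261 and 593, a replicate block 284 and 747, and the fit without the 2 deepest libraries 781 higher. For C-178 plus CMA against C-178, the 2 groups alone gave 738 and 600, and a replicate block 1563 and 1460 (1365 and 1694 with the length and GC trend removed, 1448 and 1333 on thinned reads). For C-178 plus CMA against no stimulation the 2 groups alone gave 809 and 722. For the interaction, positive calls were 293 without a filter, 296 without a trend, 1438 with array weights and 778 in DESeq2, and negative calls 1673 with array weights and 446 with the length and GC trend removed. With an estimated correlation the lists called were 0, 1, 2, 0, 0 and 0 by camera, in the order of the report. For all of these the cause was not tested, but the fits of the 2 groups alone differ from the full fit only in the estimate of the spread. Leaving out 1 library gave, for CMA against no stimulation, 1761 (without CMA 2) to 2652 (without C178_CMA 3) higher and 1536 (without no_stimulation a) to 2500 (without C178_CMA 3) lower. For C-178 it gave 4 (without no_stimulation a) to 24 (without C178_CMA 3) higher and 0 to 5 (without C178_CMA 3) lower by limma. For C-178 plus CMA against CMA it gave 597 (without CMA 2) to 2179 (without C178_CMA 2) higher and 747 (without CMA 2) to 2532 (without C178_CMA 2) lower. Against C-178 it gave 1056 (without C178 2) to 2114 (without C178_CMA 2) and 885 to 2067, against no stimulation 889 (without no_stimulation a) to 1670 (without C178_CMA 2) and 762 to 1672, and for the interaction 122 (without no_stimulation a) to 1681 (without C178_CMA 2) and 209 (without CMA 2) to 2018 (without C178_CMA 2). The share of the agonist response kept by interferon-stimulated genes ran from 80.6% (without C178_CMA 2) to 90% (without C178_CMA 3), the correlation of agonist effects from 0.63 (without C178_CMA 2) to 0.80 (without C178_CMA 3), and that of the C-178 effects from -0.25 (without C178 1) to -0.04 (without C178 2). Scaling moved the balance of calls: the share higher in C-178 plus CMA against C-178 went from 51.8% to 41.7% (1351 and 1892) with quantile normalisation, and that for CMA against no stimulation from 52.1% to 41.9% (1995 and 2769) with the length and GC trend removed, where the median over all genes moved from -0.01 to -0.11 (-0.115 with quantile normalisation). In C-178 plus CMA against CMA the balance turned from more falls (1217 and 1543) to more rises with quantile normalisation (1405 and 1303) and with the length and GC trend removed (1286 and 1103). Depth limits low genes: 3 reads over the CMA group equal 1.8092 normalised counts.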

Other observations

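The tests of length, GC content and depth for NRF2 targets in this part were chosen only after the result was seen. Within the macrophage list, Cebpa fell with CMA from 1782 to 228.1 (log2 change -2.96 ± 0.36) and Maf from 9852 to 2620 (-1.91), and Cebpa (1.77 ± 0.36) was higher with C-178 plus CMA than with CMA. These 2 genes do not stand for the list, which was not called with CMA (median -0.03, 3 up and 7 down of 25, 3 and 8 over the list alone, adjusted p = 0.642). The class II genes H2-Aa (1.09 ± 0.22), H2-Ab1 (1.00 ± 0.22) and H2-Eb1 (1.01 ± 0.16) were higher with C-178 plus CMA than with CMA, while Ciita, which encodes their transactivator, was lower (-1.79). The antigen presentation list had a median of 0.18 there, which turned to -0.05 with the length and GC trend removed, and was not called (adjusted p = 0.167). Hdc, which encodes the enzyme that makes histamine, rose with CMA from 5.21 to 258.4 normalised counts (5.38), although the mast cell gene Kit stood at only 9.278 without stimulation. The p53 targets moved in both directions with CMA, with Cdkn1a from 6528 to 20840 and Sesn1 from 4715 to 349.9.

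In C-178 plus CMA against no stimulation further lists were called by camera, none of them with an estimated correlation: chemokine genes (median 2.14, adjusted p = 2.3e-05, and 0.124 with an estimated correlation), cytokine genes (0.77, adjusted p = 0.000302, and 0.168 with an estimated correlation), feedback regulators (1.29, adjusted p = 0.000302, and 0.222 with an estimated correlation) and inflammasome and cell death genes (0.47, adjusted p = 0.00388, and 0.207 with an estimated correlation). Also called were ribosomal protein genes (0.30, or 0.13 with quantile normalisation and 0.16 with the length and GC trend removed, adjusted p = 0.0063, and 0.676 with an estimated correlation), NF-κB targets (0.38, adjusted p = 0.0077, and 0.482 with an estimated correlation), immediate early genes (-0.54, adjusted p = 0.0139, and 0.578 with an estimated correlation), targets of the sterol receptor LXR (-0.30, adjusted p = 0.0308, and 0.437 with an estimated correlation) and cell cycle genes (-0.58, adjusted p = 0.0475, and 0.706 with an estimated correlation). For the cell cycle genes the shift lay in C178_CMA 3 (list mean 6.183), as C178_CMA 1 and 2 (7.437 and 7.419) were close to the unstimulated libraries (7.427 to 7.495). For the ribosomal protein genes C178_CMA 1 stood apart (11.373), and C178_CMA 2 (10.725) was within the unstimulated range (10.616 to 10.775).

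NRF2 target genes such as Hmox1, Gclc, Srxn1 and Txnrd1 were higher with C-178 both without CMA (list median 0.46) and with it (0.58). With the length and GC trend removed the medians were 0.49 and 0.53, and with reads thinned to the shallowest library 0.49 and 0.55, so neither property of the libraries accounted for the shift. CMA alone left the list uncalled (median -0.19, or -0.49 with quantile normalisation, adjusted p = 0.26). The interaction of the list means was 0.04 ± 0.11, but 2 of 30 members were called with a negative interaction, and Txnrd1 went from 1.25 without CMA to 0.48 with it, so a dependence on the agonist for single members is not excluded. C-178 is a covalent binder, and reaction with the cysteines of the NRF2 repressor KEAP1 is a possible cause of the shift at 0.49, but no group here lacks STING or NRF2 and this was not tested.

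Across all genes the effects of C-178 without and with CMA correlated at -0.21 (slope -0.54), but at -0.09 with the length and GC trend removed and at -0.04 without C178 2.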
